A study of Homo sapiens with 12 samples.

How the data were processed

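Total RNA from 12 cultures of HK-2 cells was isolated with a column kit, labelled as biotinylated cRNA and hybridised to Affymetrix arrays, per the labels' protocols. Cells were seeded 24 h before treatment and treated near confluence, and control cultures received vehicle, per the labels' protocols. The labels give 4 groups of 3 biological replicates, Kbr 24 h, control 24 h, Kbr 48 h and control 48 h, and the dose only as high. The deposited log2 values were made by the authors with GCRMA (background correction from probe sequence, normalization across arrays and a summary per probe set), per the submitters' processing notes, which give no version. The values ran up to 16.2 and had nearly the same median in every array. Neither detection calls nor a genome build were given, so no coordinates are reported.

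Of 54675 probe sets, 41091 carried 1 gene symbol in the platform's annotation, 1801 carried several, 11721 carried none and 62 were Affymetrix controls. For each of 19775 genes the single-gene probe set with the highest mean was used. Symbols were compared with a reference gene table, which updated 0 probe set symbols and 2 names in the gene lists. No value was missing. Genes were tested if they exceeded a log2 value of 4 in at least 3 arrays, which kept 10574 and left out 9201. Of the tested genes 5192 had more than 1 probe set over that level, and in 13 genes at 24 h and 250 at 48 h such probe sets were called in opposite directions.

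Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 12 arrays, 8 residual and 2.87 prior degrees of freedom, two-sided). The Benjamini-Hochberg procedure was applied over all tested genes of each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were Kbr against control at 24 h, the same at 48 h, the difference between these effects, and control cultures at 48 h against 24 h. SE stands for the moderated standard error of the log2 fold change and SD for the spread over 3 arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

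Altogether 34 gene lists were fixed for the responses and cell types that such a culture could show. They cover NRF2-type, p53, ATF4, unfolded protein, heat shock, metallothionein, osmotic, G2 and mitosis, replication, histone, repair, sterol, fatty acid synthesis and oxidation, glycolysis and hypoxia, respiratory chain, ribosomal protein, ribosome biogenesis, proteasome, NF-kB, interferon, immediate early, apoptosis, autophagy and lysosome, proximal tubule, tubule injury, matrix and mesenchymal, junction, ion transport and xenobiotic metabolism genes, and markers of other nephron segments, fibroblasts, endothelium or leukocytes, and squamous epithelium. The 30 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with all other genes. None of the list calls held with an estimated correlation. Member counts are given over all genes tested and adjusted over the list alone.

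The comparisons, the lists and the rule for naming genes, and the tests and alternatives not named in the text as later choices, were chosen before the data were examined. The rule took the 12 largest rises and the 12 largest falls at each time among called genes whose Kbr and control arrays did not overlap, the 5 largest each way among called genes for the other comparisons, and the 3 members of each list with the largest change at each time, called ones first. It named 163 genes. Genes outside it were chosen after their values were seen.

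The labels give the same replicate numbers in every group. After group means were removed, the 18 pairs of arrays with the same number correlated between 0.232 and 0.633 and the 36 pairs with different numbers between -0.378 and -0.004, so the numbers pair the arrays. The fit was therefore repeated with the number as a block (6 residual degrees of freedom), and its value stands beside a result where it changes the call or moves a count by more than 1.5 times. It also stands beside the counts of called genes at 24 h and 48 h.

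The alternatives were an adjusted p under 0.01, a change of at least 2-fold, no expression filter or a log2 value over 6, the mean of all probe sets of a gene, each probe set on its own, unsuffixed probe sets preferred, arrays centred on their median, quantile normalization, an offset of 32 on the linear scale, a trended and robust prior, array weights, only the groups compared, the replicate block, each array left out in turn, and for lists an estimated correlation and limma's fry. Unsuffixed probe sets lack the endings _x_at and _s_at, and genes with no other probe set kept a suffixed one. RNA quality was checked on control probe sets with exact permutation tests. The fits were tested on simulated data with 200 changed genes.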

Results

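Messenger RNA levels were measured in HK-2 cells, an immortalised line of human kidney proximal tubule epithelial cells, after exposure to a high dose of a compound that the labels call Kbr or to its vehicle. The submitters' stated aim was to find signatures of toxicity in this line; other compounds of that programme were not analysed here. Each culture was sampled at 24 h or 48 h, with 3 biological replicates per group, so that the 12 Affymetrix arrays fall into 4 groups (Kbr 24 h, control 24 h, Kbr 48 h and control 48 h). The concentration is not given in the sources used here. Each array reports 54675 probe sets as log2 GCRMA values, an array summary corrected for background binding. Medians of the 12 arrays lay between 2.89 and 2.96, and 39.1% to 39.9% of probe sets exceeded a log2 value of 4. The number of arrays limits the precision of each value below, which is a mean ± SD over 3 arrays unless stated otherwise. Genes are identified by symbol and, for those described most fully, by Affymetrix probe set.

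The arrays separated first by treatment. The leading principal component, with 67.7% of the variance, ran from scores between 23.1 and 48.7 in the 6 control arrays to scores between -20.6 and -55.7 in the 6 Kbr arrays. The second, with 13.9%, placed Kbr 48 h replicate 3 at 7.02, apart from the other Kbr 48 h arrays at -23.8 and -23.6. Its root mean square deviation from its group mean was 0.290 on the log2 scale, against 0.164 to 0.228 in the other 11 arrays. Probe sets for 18S and 28S ribosomal RNA, which carry no long poly-A tail, were higher in every Kbr array than in every control array of the same time. The 18S difference was 0.49 at 24 h and 0.51 at 48 h on the log2 scale, and the 28S difference was 0.38 and 0.46. The exact permutation p was 0.1 each, two-sided, the smallest that 3 against 3 arrays allow, and 0.35 after adjustment over 14 quality measures. This test took no account of the pairing by replicate number. The 3' to 5' log2 signal differences of GAPDH were -0.10 ± 0.04 in Kbr and -0.11 ± 0.05 in control arrays at 24 h, and -0.11 ± 0.04 and -0.09 ± 0.05 at 48 h. Those of ACTB were 0.93 ± 0.20 and 0.83 ± 0.18 at 24 h, and 1.04 ± 0.19 and 0.87 ± 0.23 at 48 h. Kbr and control arrays overlapped in both measures.

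**Figure D1:**
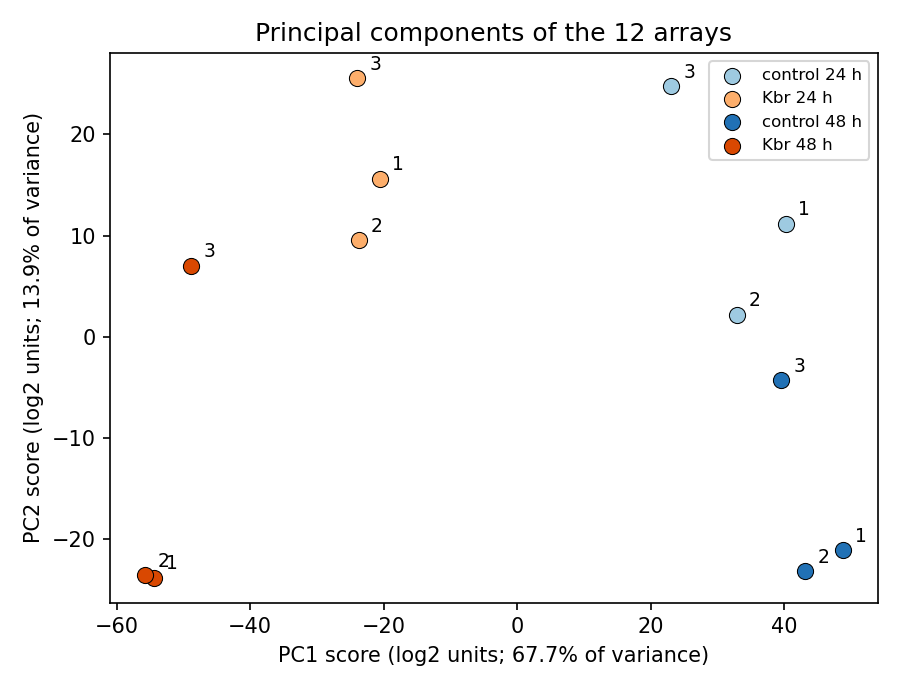
Scores of the 12 arrays on the first principal components of the tested genes (log2 units), one point per array, coloured by group and numbered by replicate. Control arrays lie between 23.1 and 48.7 on the horizontal axis and Kbr arrays between -20.6 and -55.7, and Kbr 48 h replicate 3 lies at 7.02 on the vertical axis against -23.8 and -23.6 for the other Kbr 48 h arrays.

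The comparison of Kbr with control cultures at 24 h asked which transcripts had changed after the shorter exposure. The largest rise among called genes was in HMOX1 (probe set 203665_at), the haem oxygenase that breaks down haem, which went from 7.91 ± 0.30 in control to 11.32 ± 0.24 in Kbr cultures, a log2 fold change of 3.41 (SE 0.24, adjusted p = 1.68e-05). GCLM (203925_at), a subunit of the enzyme that starts glutathione synthesis, went from 10.19 ± 0.35 to 12.65 ± 0.19 (2.47, SE 0.19, adjusted p = 3.09e-05), and TXNRD1, thioredoxin reductase, rose by 1.76. Of 25 tested members of the NRF2-type antioxidant list, 18 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 fold change of 0.86. The exception was ABCC3, an organic anion exporter, at -1.30 (named after its value was seen). The list stood apart from the other genes in limma's camera test (adjusted p = 5.85e-11), a call that was lost with an estimated correlation between genes (adjusted p = 0.148).

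Cytosolic heat shock genes rose in the same cultures, 12 of 15 tested members and none lower, also when adjusted over the list alone. Their median was 0.76, with a camera adjusted p of 9.01e-09 (adjusted p = 0.21 with an estimated correlation). CHORDC1, an HSP90 co-chaperone, rose by 1.93 (SE 0.18), HSPH1, an HSP110-family chaperone, by 1.62 (SE 0.10) and the co-chaperone BAG3 by 1.58 (SE 0.20). Of 23 proteasome subunit genes 14 rose (17 adjusted over the list alone) and 0 fell, with PSMD12 at 1.11 (SE 0.18), PSMC4 at 0.81 (SE 0.17) and PSMC1 at 0.75 (SE 0.11). The proteasome median was 0.41 (camera adjusted p = 1.79e-08; adjusted p = 0.323 with an estimated correlation). Ribosome biogenesis genes, which make and assemble ribosomes, rose in 14 of 19 cases (15 adjusted over the list alone) and fell in 0, with a median of 0.58 (camera adjusted p = 1.47e-07; adjusted p = 0.21 with an estimated correlation). The rRNA methyltransferase NOP2 rose by 1.00 (SE 0.13) and RRS1 by 0.86 (SE 0.16). In the G2 and mitosis list 15 of 30 genes rose and 0 fell, the same numbers adjusted over the list alone, with a median of 0.34 (camera adjusted p = 1.35e-06; adjusted p = 0.489 with an estimated correlation). Among them were the mitotic cyclin CCNB1 at 0.68 (SE 0.15) and the kinesin KIF23 at 0.79 (SE 0.19). The control probe sets for 18S and 28S ribosomal RNA were also higher, as given above, and no link between them and these genes was tested.

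The others of the 12 largest rises at 24 h included the vasodilator peptide gene ADM (2.65, SE 0.30), GPAT3 of glycerolipid synthesis (2.48, SE 0.23), OSGIN1 (2.39, SE 0.54), the zinc finger gene ZFAND2A (2.20, SE 0.21), TRIM16 (2.02, SE 0.11) and PMAIP1 (1.76, SE 0.23), a BCL2-family gene that promotes cell death. FOSL1, an AP-1 subunit, rose by 2.10 (SE 0.68, adjusted p = 0.0364) and the cystine transporter gene SLC7A11 by 2.07 (SE 0.56, adjusted p = 0.0172). The FOSL1 call ended without Kbr 24 h replicate 1 (adjusted p = 0.0929) or 3 (0.106), without control 24 h replicate 1 (0.0655) or 2 (0.122), and with no expression filter (0.107). The SLC7A11 call ended without Kbr 24 h replicate 1 (adjusted p = 0.0554) or 2 (0.0518), without control 24 h replicate 1 (0.0569), and with no expression filter (0.0591).

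The largest fall among called genes at 24 h was in SCEL (206884_s_at), a component of the cornified envelope, which went from 10.13 ± 0.61 in control to 6.68 ± 0.51 in Kbr cultures (-3.44, SE 0.36, adjusted p = 0.000162). PPL (203407_at), a desmosome-associated plakin, fell by 3.27 (SE 0.19, adjusted p = 5.55e-06) from 7.27 ± 0.36 in control cultures, and CGN, the tight junction protein cingulin, from 6.57 ± 0.19 to 3.82 ± 0.40 (-2.75, SE 0.29). Of 15 epithelial junction genes 6 fell (9 adjusted over the list alone) and 0 rose, with a median of -0.46 (camera adjusted p = 0.016; adjusted p = 0.21 with an estimated correlation). CDH1, the epithelial cadherin (-2.17, SE 0.37), CLDN2, a claudin of leaky epithelia (-1.53, SE 0.27), and JUP, plakoglobin (-1.51, SE 0.20), were among those that fell. Only 8 of 29 proximal tubule genes passed the expression filter, and 5 of them fell (8 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 0.00496; adjusted p = 0.21 with an estimated correlation). They included the cystine and dibasic amino acid transporter subunit SLC3A1 (-1.80, SE 0.30), CDH6, kidney cadherin (-1.06, SE 0.23), and GATM of creatine synthesis (-0.91, SE 0.15). With no expression filter the median of the proximal tubule list was 0.02 and the call ended (adjusted p = 0.653).

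Of 22 genes linked to tubule injury and regeneration, 5 fell and 0 rose, the same adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.0296; adjusted p = 0.403 with an estimated correlation). The leukocyte adhesion molecule VCAM1 (-2.72, SE 0.28), keratin KRT19 (-1.51, SE 0.21) and the transcription factor gene SOX4 (-1.02, SE 0.13) were among the falls. That list's call ended without Kbr 24 h replicate 2 (adjusted p = 0.0516) or control 24 h replicate 3 (0.0567). The list of TGF-beta, matrix and mesenchymal transition genes had 7 of 23 members lower and 0 higher, also adjusted over the list alone, with a median of -0.44 (camera adjusted p = 0.0355; adjusted p = 0.613 with an estimated correlation). Its leading members differ in kind: CDH1 marks epithelia, whereas COL1A1 (-2.09, SE 0.21) encodes a fibrillar collagen. The call ended without Kbr 24 h replicate 2 (adjusted p = 0.0912) or control 24 h replicate 1 (0.0755) or 3 (0.0602), when all probe sets of a gene were averaged (0.0638), and with unsuffixed probe sets preferred (0.0613).

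Of 18 genes of cholesterol synthesis and uptake 8 fell (10 adjusted over the list alone) and 0 rose, with a median of -0.57 (camera adjusted p = 0.000567; adjusted p = 0.21 with an estimated correlation). The sterol reductase TM7SF2 fell by 1.92 (SE 0.23) and INSIG1, a regulator of sterol synthesis, by 0.93 (SE 0.13). Of 10 fatty acid synthesis genes 7 fell and 2 rose, also adjusted over the list alone, although the list itself was not called (median -0.46, camera adjusted p = 0.0506). ACSS2, which makes acetyl-CoA from acetate, fell by 1.79 (SE 0.15) and the lipogenic transcription factor gene SREBF1 by 1.11 (SE 0.16). In the fatty acid oxidation list 7 of 17 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.31. That list was not called (camera adjusted p = 0.0741) but was with the replicate number as a block (adjusted p = 0.044). That call was lost with an estimated correlation in the same blocked design (adjusted p = 0.274). Respiratory chain subunits had a small negative median of -0.20, with 4 of 27 lower, 0 higher, and 0 either way adjusted over the list alone (camera adjusted p = 0.0334; adjusted p = 0.558 with an estimated correlation). The respiratory chain call ended without Kbr 24 h replicate 1 (adjusted p = 0.0677), control 24 h replicate 1 (0.0507) or 2 (0.0974), after median centring (0.168), with probe sets averaged (0.094) and with unsuffixed probe sets preferred (0.203).

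Other leading falls at 24 h were HOGA1 of hydroxyproline breakdown (-3.34, SE 0.46), ENDOD1 (-3.22, SE 0.17), the ectonucleotidase ENPP3 (-3.13, SE 0.59), TXNIP, an inhibitor of thioredoxin (-2.92, SE 0.59), C1RL (-2.90, SE 0.33), the transcription factor genes HLF (-2.82, SE 0.32) and RUNX2 (-2.79, SE 0.33), the water and glycerol channel AQP3 (-2.78, SE 0.44), and SLC34A2, a phosphate transporter (-2.78, SE 0.68). The SLC34A2 call ended when an offset of 32 was added on the linear scale (adjusted p = 0.0541).

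Lists that were not called at 24 h mostly held members going both ways. Of 22 p53 targets 3 rose and 6 fell, with the nucleotide excision repair genes DDB2 (-2.28, SE 0.23) and XPC (-1.05, SE 0.15) among the falls. Of 34 S phase and replication genes 3 rose and 11 fell, the latter including POLA1 (-0.93, SE 0.12) and PRIM1 (-0.86, SE 0.15), subunits of the DNA polymerase alpha and primase complex. Of 19 DNA repair genes 4 rose, among them the glycosylase gene NEIL3 (from 8.61 ± 0.25 in control to 10.11 ± 0.02 in Kbr cultures), and 4 fell, among them XRCC1 (-1.18, SE 0.22). Interferon-stimulated genes split as well, 4 of 14 higher, with IFIT1 at 1.64 (SE 0.38) and IFIT2 at 1.38 (SE 0.30), and 2 lower, with IFITM1 at -1.53 (SE 0.35). Of 17 immediate early genes 3 rose, with the phosphatase gene DUSP5 at 1.18 (SE 0.21), and 4 fell (5 adjusted over the list alone), with EGR1 at -1.82 (SE 0.15). Adjusted over the list alone, counts for p53, ATF4, unfolded protein response, replication, repair and interferon genes did not differ. Camera adjusted p values of these lists lay between 0.126 for replication and 0.948 for repair. The unfolded protein response list had 0 of 18 members past the test, with a median of 0.02 and a list adjusted p of 0.227. The chaperone HSPA5 stood at 0.63 (SE 0.29, adjusted p = 0.119). The fit shares its spread over the 4 groups, so the unlike Kbr 48 h arrays of this list widen the SE at 24 h. In HSPA5 the Kbr 24 h arrays read 13.7 to 13.9 against 12.9 to 13.4 in control arrays, and in DNAJC3 8.68 to 8.90 against 8.06 to 8.19. In SDF2L1 they overlapped, 7.13 to 7.40 against 6.63 to 7.41. The ATF4 list had 2 of 26 higher and 2 lower, with the amino acid transporter subunit SLC3A2 at 1.75 (SE 0.37) and a list adjusted p of 0.616. Median and camera direction differed in sign for the ATF4 (median -0.09), repair (-0.10), interferon (-0.01) and NF-kB (-0.12) lists, and median and mean for the ATF4, interferon and ribosomal protein lists.

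Of 8 metallothionein-list genes 2 fell at 24 h (5 adjusted over the list alone), MT1F by 0.72 (SE 0.17) and MT1E by 0.60 (SE 0.15), with a camera adjusted p of 0.0809. MT1G stood at -0.55 (adjusted p = 0.0597, or 0.0112 with the replicate block). Of 8 osmotic stress genes 1 rose, HSPA4L at 0.43 (SE 0.11), and 1 fell (1 and 0 adjusted over the list alone), with a list adjusted p of 0.905. In the osmotic list the inositol transporter SLC5A3 stood at 0.91 (SE 0.36, adjusted p = 0.0739, or 0.00516 with the block). Of 24 glycolysis and hypoxia genes 3 rose and 3 fell, PDK1 by 0.89 (SE 0.14), with a list adjusted p of 0.459. Of 23 autophagy and lysosome genes 5 rose, led by the autophagy receptor SQSTM1 (1.43, SE 0.18), and 2 fell (list adjusted p = 0.332). Of 14 apoptosis genes 2 rose and 1 fell, MCL1 by 0.54 (SE 0.12, but adjusted p = 0.394 with unsuffixed probe sets preferred), with a list adjusted p of 0.465. Of 16 sodium, potassium and chloride transport genes 2 rose, ATP1B3 at 0.48 (SE 0.09) among them, and 3 fell, with SLC26A2 at -1.03 (SE 0.17) and a list adjusted p of 0.905. Of 10 xenobiotic metabolism genes 3 fell (4 adjusted over the list alone), with the sulfotransferase SULT1A1 at -0.96 (SE 0.15), and the list adjusted p was 0.274. Of 5 replication-dependent histone genes H2BC12 rose by 0.86 (SE 0.16), with a list adjusted p of 0.335; H2BC6 stood at 0.47 (adjusted p = 0.121, or 0.0395 with the block). Except where given, counts adjusted over the list alone were the same. None of 17 ribosomal protein genes (list adjusted p = 0.905) or 16 NF-kB responsive genes (list adjusted p = 0.905) passed the test. In them RPL3 stood at -0.24 (adjusted p = 0.0554, or 0.0189 with the block) and the chemokine gene CCL2 at -1.31 (adjusted p = 0.0841, or 0.0424 with the block).

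Markers of other cell types were mostly below the expression filter. Of 4 tested markers of other nephron segments 2 fell at 24 h, AQP3 and SCNN1A (-0.62, SE 0.14; -0.18 and adjusted p = 0.149 with probe sets averaged). All 3 tested fibroblast markers fell, COL1A1, LUM (adjusted p = 0.072 without Kbr 24 h replicate 3, 0.0753 without control 24 h replicate 1 and 0.0512 with no filter) and the proteoglycan gene DCN, from 12.21 ± 0.30 to 11.22 ± 0.20. Of 2 squamous markers SFN stood at -0.35 (adjusted p = 0.0323, and between 0.0577 and 0.102 without any of 5 single arrays, 0.102 with median centring and 0.0802 with probe sets averaged), and the only tested endothelial or leukocyte marker, TEK, stood at 0.07 (adjusted p = 0.587). Adjusted over each list alone the counts did not differ.

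Over all 10574 tested genes, limma called 3429 genes at 24 h at an adjusted p under 0.05, 1315 higher and 2114 lower in Kbr, or 5072 with the replicate number as a block. Of the 3429 genes, 766 changed at least 2-fold, 129 up and 637 down (232 and 403 after quantile normalization, 74 and 300 with an offset of 32). The Kbr and control arrays did not overlap in 51.6% of tested genes, against 10% by chance for 3 against 3 unpaired arrays. That chance value takes no account of the pairing by replicate number. Of the 637 strong falls, 71 had all 3 Kbr arrays at or under a log2 value of 4. The share of falls depended on array scaling, 61.7% as deposited, 50.7% with arrays centred on their medians and 43.8% after quantile normalization, where 2155 genes were higher, and the count was 2255 without control 24 h replicate 1.

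The same comparison at 48 h described the longer exposure. HMOX1 went from 7.78 ± 0.40 in control to 11.56 ± 0.36 in Kbr cultures (3.77, SE 0.24, adjusted p = 1.13e-06) and GCLM from 9.67 ± 0.30 to 12.86 ± 0.05 (3.19, SE 0.19, adjusted p = 8.27e-07). Of 25 NRF2-type genes 22 rose and 1, ABCC3 again (-2.26), fell, the same adjusted over the list alone, with a median of 1.18 (camera adjusted p = 4.48e-07; adjusted p = 0.198 with an estimated correlation). Heat shock genes rose in 13 of 15 cases and fell in 1, also adjusted over the list alone, the fall being the small chaperone CRYAB at -0.58 (named after its value was seen). Their median was 0.92 (camera adjusted p = 1.81e-05; adjusted p = 0.347 with an estimated correlation), with HSPH1 at 2.26 (SE 0.10) and CHORDC1 at 2.79 (SE 0.18). Of 23 proteasome genes 21 rose (22 adjusted over the list alone) and 0 fell, with a median of 0.66 (camera adjusted p = 4.48e-07; adjusted p = 0.406 with an estimated correlation) and PSMD12 at 2.01 (SE 0.18). Ribosome biogenesis genes rose in 16 of 19 cases and fell in 0, also adjusted over the list alone, with a median of 0.95 (camera adjusted p = 3.18e-06; adjusted p = 0.347 with an estimated correlation) and NOP2 at 1.58 (SE 0.13). Of 30 G2 and mitosis genes 24 rose (25 adjusted over the list alone) and 1, the kinesin KIF20A at -0.74, fell. The median of that list was 0.64 (camera adjusted p = 5.46e-06; adjusted p = 0.462 with an estimated correlation), with CCNB1 at 1.19 (SE 0.15) and the spindle checkpoint kinase TTK at 1.09 (SE 0.15). Ribosomal RNA probe sets were again higher in every Kbr array.

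Genes of the unfolded protein response, which include chaperones of the endoplasmic reticulum, rose at 48 h, 12 of 18 and none lower (13 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 0.000688; adjusted p = 0.504 with an estimated correlation). SDF2L1 (218681_s_at), part of a chaperone complex of that compartment, went from 6.33 ± 0.20 to 9.78 ± 1.46 (3.45, SE 0.54, adjusted p = 0.000262), DNAJC3 rose by 2.02 (SE 0.37) and DNAJB11 by 1.87 (SE 0.23). Of 26 ATF4 and integrated stress response genes 10 rose and 2 fell, also adjusted over the list alone, with a median of 0.53 and no call for the list (camera adjusted p = 0.0678). ATF3 (202672_s_at), a stress-induced transcription factor gene, showed the largest rise of all, from 5.88 ± 0.75 to 10.53 ± 2.27 (4.65, SE 0.93, adjusted p = 0.00128), and the amino acid transporter genes SLC7A5 and SLC7A11 rose by 2.90 (SE 0.65) and 2.77 (SE 0.56). The Kbr 48 h arrays differed among themselves in both groups. The unfolded protein response list had a median of 1.57 and 1.13 above the control mean in replicates 1 and 2 and of 0.10 in replicate 3. The ATF4 list stood at 1.11, 0.75 and -0.49 in the same order. ATF3 itself read 12.2, 11.5 and 7.94, and SDF2L1 10.9, 10.4 and 8.12. Replicate 3 was not low throughout, since its NRF2-type, heat shock and proximal tubule medians were 1.10, 1.11 and -1.85. Without that array, 15 of 18 unfolded protein response and 16 of 26 ATF4-list genes rose, and the ATF4 list was called (adjusted p = 0.000536), as it was without control 48 h replicate 1 (0.0154).

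**Figure D2:**
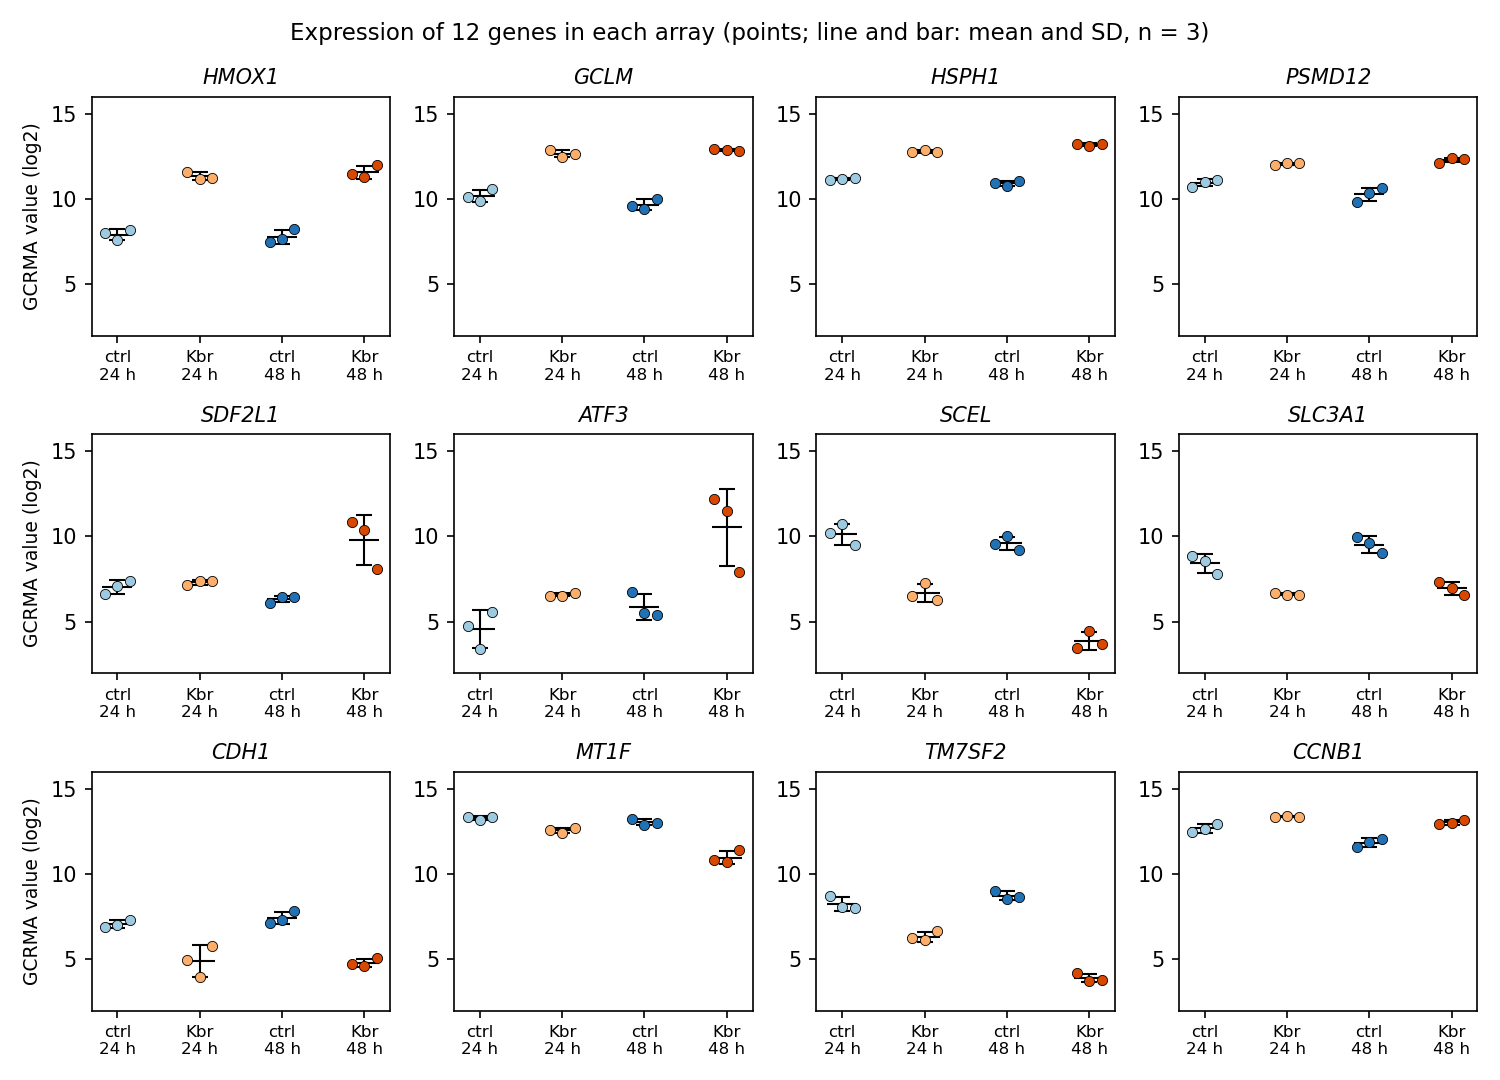
Log2 GCRMA values of 12 genes in each array, in the groups control 24 h, Kbr 24 h, control 48 h and Kbr 48 h; points are arrays, and the line and bar are the mean and SD of 3 arrays. HMOX1 lies at 7.91 and 7.78 in control and 11.32 and 11.56 in Kbr cultures, whereas in ATF3 the Kbr 48 h arrays spread from 7.94 to 12.2.

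Among the other leading rises at 48 h were ADM (4.30, SE 0.30), FOSL1 (3.49, SE 0.68), DDIAS, an apoptosis suppressor induced by DNA damage (3.36, SE 0.31), ZFAND2A (3.32, SE 0.21), the hyaluronan-binding protein gene TNFAIP6 (3.19, SE 0.35), OSGIN1 (2.92, SE 0.54) and GPAT3 (2.83, SE 0.23). Of 17 immediate early genes 9 rose and 4 fell, also adjusted over the list alone, with DUSP5 at 2.65 (SE 0.21) and EGR1 at -2.60 (SE 0.15). The immediate early list had an adjusted p of 0.0578, or 0.0319 without control 48 h replicate 1. Of 22 p53 targets 8 rose and 8 fell, among them the growth factor gene GDF15 (2.07, SE 0.24) and DDB2 (-2.59, SE 0.23), with a median of -0.06, although camera's direction was upward (adjusted p = 0.943). Replication genes also split, 10 of 34 higher and 9 lower (list adjusted p = 0.319), with the replication licensing gene CDC6 at 2.80 (SE 0.26) and MCM10 at 2.66 (SE 0.23). Of 19 repair genes 5 rose and 5 fell, with NEIL3 at 2.33 (SE 0.17) and the glycosylase NTHL1 at -2.78 (SE 0.45; list adjusted p = 0.344). Of 24 glycolysis and hypoxia genes 6 rose and 4 fell (6 and 3 adjusted over the list alone), with the angiogenic factor VEGFA at 2.22 (SE 0.37), the glucose transporter SLC2A1 at 1.53 (SE 0.15) and a list adjusted p of 0.156. Of 14 apoptosis genes 4 rose, PMAIP1 by 2.72 (SE 0.23), and 1 fell (list adjusted p = 0.319), and of 23 autophagy and lysosome genes 7 rose and 3 fell, with SQSTM1 at 1.47 (SE 0.18; list adjusted p = 0.258). Except where given, counts adjusted over the list alone were the same.

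All 8 tested proximal tubule genes fell at 48 h, also adjusted over the list alone. The median was -1.88 (camera adjusted p = 0.000688; adjusted p = 0.198 with an estimated correlation). With no expression filter it was 0.01 and the call ended (adjusted p = 0.133). CDH6 went from 12.57 ± 0.36 to 10.01 ± 0.31 (-2.57, SE 0.23), SLC3A1 from 9.52 ± 0.49 to 6.97 ± 0.37 (-2.55, SE 0.30) and the angiotensinogen gene AGT from 8.06 ± 0.28 to 5.83 ± 0.34 (-2.23, SE 0.22). Of 22 tubule injury and regeneration genes 14 fell and 2 rose, also adjusted over the list alone, with a median of -0.70 (camera adjusted p = 0.0333; adjusted p = 0.462 with an estimated correlation). VCAM1 fell by 3.37 (SE 0.28) and KRT19 by 1.95 (SE 0.21), whereas the rises were the matricellular gene CCN2 (1.45) and keratin KRT18 (0.43), both named after their values were seen. The call of the injury list ended without Kbr 48 h replicate 1 (adjusted p = 0.0591) or control 48 h replicate 3 (0.0535). Of 15 junction genes 8 fell and 0 rose (8 and 1 adjusted over the list alone), with CLDN2 at -2.94 (SE 0.27) and CDH1 at -2.60 (SE 0.37), but the list was not called (adjusted p = 0.07). The matrix and mesenchymal list, with 12 of 23 lower and 1 higher (10 and 1 adjusted over the list alone), had an adjusted p of 0.0678, or 0.0295 with the replicate block. With the block and an estimated correlation it was 0.391. In it COL1A1 fell by 2.66 (SE 0.21) and LTBP2, a TGF-beta binding protein gene, by 2.07 (SE 0.32).

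Metallothionein genes, which encode metal-binding proteins, fell at 48 h in 7 of 8 cases, also adjusted over the list alone. MT1E, MT1F and MT1G were read by probe sets ending in _x_at. How far the list members are separate measurements was not tested, here or in the difference of effects. The median was -1.62 (camera adjusted p = 0.00344; adjusted p = 0.462 with an estimated correlation), and the medians per array were -1.78, -1.92 and, in replicate 3, -1.09. MT1F fell from 13.02 ± 0.17 to 10.96 ± 0.37 (-2.06, SE 0.17) and MT1E from 13.42 ± 0.13 to 11.70 ± 0.33 (-1.72, SE 0.15). Cholesterol genes fell in 12 of 18 cases and rose in 1, the synthesis enzyme NSDHL (0.64, named after its value was seen), also adjusted over the list alone. Their median was -0.71 (camera adjusted p = 0.0065; adjusted p = 0.347 with an estimated correlation), with TM7SF2 from 8.73 ± 0.26 to 3.90 ± 0.26 (-4.82, SE 0.23) and the lanosterol synthase gene LSS at -1.66 (SE 0.14). Of 17 fatty acid oxidation genes 12 fell and 1, the lipid droplet gene PLIN2 (0.76), rose, also adjusted over the list alone. The median was -0.58 (camera adjusted p = 0.00355; adjusted p = 0.198 with an estimated correlation), with ECI1 at -1.64 (SE 0.12) and ACADVL at -1.51 (SE 0.17). Fatty acid synthesis genes fell in 7 of 10 cases and rose in 2, also adjusted over the list alone, with no call (adjusted p = 0.0645), ACSS2 at -2.70 (SE 0.15) and SREBF1 at -1.68 (SE 0.16). Respiratory chain genes fell in 13 of 27 cases and rose in 0, also adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.0254; adjusted p = 0.462 with an estimated correlation). NDUFV1 fell by 1.04 (SE 0.21). The respiratory call ended without Kbr 48 h replicate 1 (adjusted p = 0.0591) or control 48 h replicate 3 (0.0531), with median centring (0.0908), with probe sets averaged (0.0653) and with unsuffixed probe sets preferred (0.248).

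The largest falls at 48 h were in SCEL, from 9.60 ± 0.39 to 3.88 ± 0.50 (-5.72, SE 0.36), and EFEMP1, a matrix glycoprotein gene, from 8.37 ± 0.14 to 3.00 ± 0.70 (-5.37, SE 0.31). The other leading falls were in ENPP3 (-5.05, SE 0.59), ENDOD1 (-4.85, SE 0.17), the adaptor gene BLNK (-4.82, SE 0.41), the iron exporter SLC40A1 (-4.49, SE 0.33), C1RL (-4.46, SE 0.33), the cilium-associated gene CYS1 (-4.44, SE 0.31), the organic anion transporter SLC17A3 (-4.39, SE 0.28) and HLF (-4.24, SE 0.32). The complement gene CFB fell by 4.29 (SE 0.28), but not in the unsuffixed probe set used instead (-0.05), which had a lower mean signal. Several Kbr means, such as 2.76 ± 0.20 in ENPP3 and 2.13 ± 0.15 in ENDOD1, lay at or below the array median.

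Uncalled lists at 48 h with mostly lower members were osmotic stress genes, 5 of 8 lower and 1 higher, with the kinase gene SGK1 at -1.85 (SE 0.15; list adjusted p = 0.293), and xenobiotic metabolism genes, 6 of 10 lower and 0 higher, with SULT1A1 at -1.75 (SE 0.15; list adjusted p = 0.239). Of 14 interferon-stimulated genes 5 fell and 0 rose, IFITM1 by 2.90 (SE 0.35), with a list adjusted p of 0.258. Of 16 ion transport genes 7 fell and 2 rose, with KCNJ15 at -1.06 (SE 0.14; list adjusted p = 0.258). Of 16 NF-kB responsive genes 3 fell, CCL2 by 2.75 (SE 0.54), and 1 rose (3 and 0 adjusted over the list alone; list adjusted p = 0.689), the median being 0.10 and the mean -0.07. Of 17 ribosomal protein genes 2 fell (1 adjusted over the list alone), RPL3 by 0.44 (SE 0.09), with a list adjusted p of 0.716. None of 5 histone genes passed the test (list adjusted p = 0.489). Of the cell type markers, 3 of 4 nephron markers and all 3 fibroblast markers fell, with AQP3 at -3.59 (SE 0.44), DCN at -1.90 (SE 0.16) and LUM at -2.00 (SE 0.22), and none of the squamous, endothelial or leukocyte markers passed the test. The third nephron marker, PODXL at -0.43, lost its call without any of 4 single arrays (adjusted p between 0.0567 and 0.107) and stood at 0.025 after quantile normalization (adjusted p = 0.883). Counts adjusted over the list alone were otherwise the same.

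**Figure D3:**
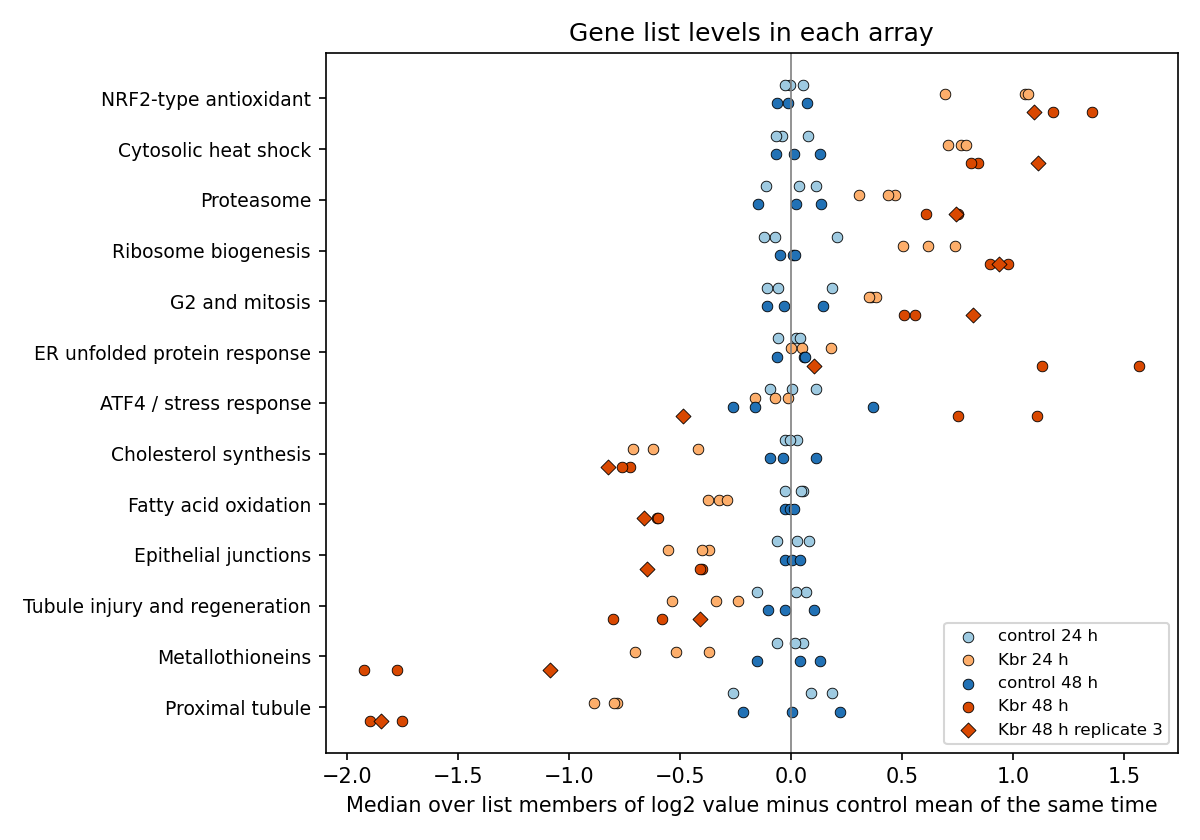
Level of 13 gene lists in each array, as the median over list members of the log2 value minus the control mean of the same time; points are arrays, coloured by group, and the diamond is Kbr 48 h replicate 3. In the proximal tubule list the Kbr 48 h arrays lie between -1.90 and -1.75, whereas in the unfolded protein response list replicate 3 lies at 0.10 and the other Kbr 48 h arrays at 1.13 and 1.57.

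At 48 h limma called 6306 of 10574 genes, 2840 higher and 3466 lower, or 7338 with the replicate number as a block. Of the 6306 genes, 2475 changed at least 2-fold, 837 up and 1638 down (1085 and 1290 after quantile normalization, 635 and 1156 with an offset of 32). Of the 1638 strong falls, 160 had all Kbr arrays at or under a log2 value of 4. The Kbr and control arrays did not overlap in 62.8% of tested genes (10% by chance for unpaired arrays). The share of falls was 48.8% after median centring and 44.6% after quantile normalization, which moved the median of all genes by 0.14. The median of each of the 12 lists called at 48 h, like the 11 called at 24 h, kept its sign with median centring and with quantile normalization. After quantile normalization it also did so relative to the median of all genes.

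Genes changed at 24 h were largely those changed at 48 h. Of 3193 genes called at both times, 3192 changed in the same direction, 1238 higher, where independent lists would share 353, and 1954 lower, where they would share 693. Of the genes called at 24 h, 83.9% had a larger absolute log2 fold change at 48 h. Across all tested genes, which are not independent replicates, the fold changes at the 2 times correlated with a Pearson r of 0.896 and a Spearman rho of 0.896, and the slope of 48 h on 24 h over genes called at 24 h was 1.48. The 2 times had separate control arrays.

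**Figure D4:**
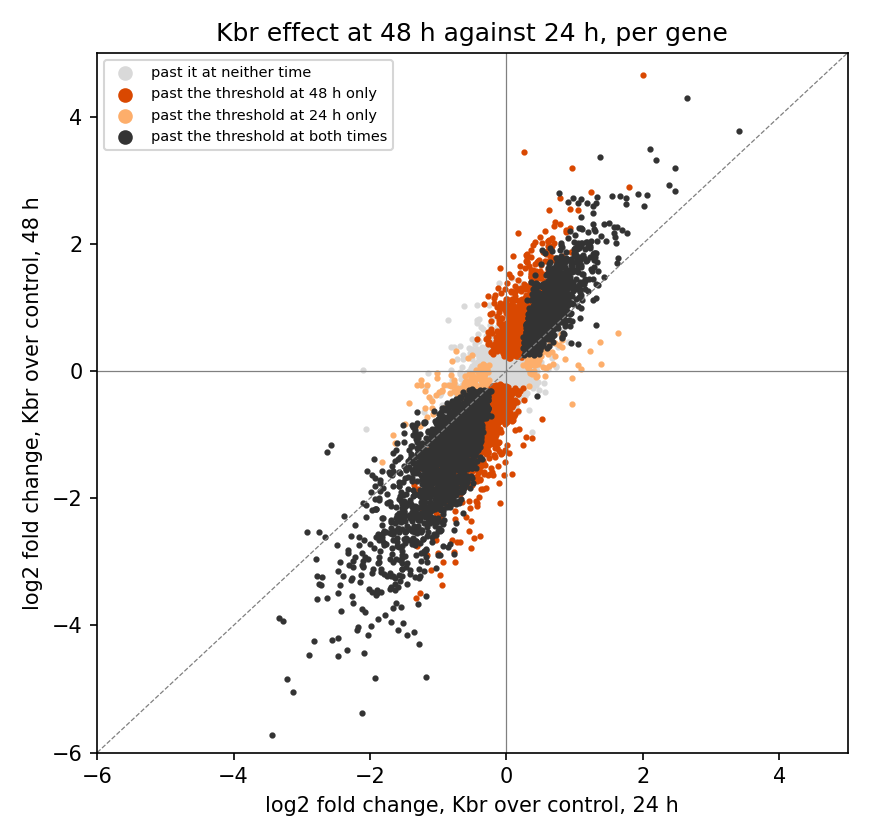
Log2 fold change of Kbr over control at 48 h (vertical axis) against 24 h (horizontal axis), one point per tested gene, coloured by the times at which it passed an adjusted p of 0.05; the dashed line marks equal change. Of 3193 genes past the threshold at both times, 3192 lie in the lower left or upper right quadrant, with an r of 0.896 over all genes.

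Whether the effect of Kbr itself differed between the times was tested as an interaction. A difference of effects can come from a change in control cultures as well as in Kbr cultures. Among called genes SDF2L1 showed the largest positive difference of effects (48 h minus 24 h), 3.19 (SE 0.76, adjusted p = 0.0399), followed by TNFAIP6 (2.22, SE 0.49), CDC6 (2.02, SE 0.37), DDIAS (1.98, SE 0.43) and the transcription factor gene ZIC2 (1.94, SE 0.46). ATF3 had a difference of 2.65 (SE 1.31) but was not called (adjusted p = 0.244). The largest negative differences among called genes were in BLNK (-3.64, SE 0.58), EFEMP1 (-3.26, SE 0.44), CFB (-3.01, SE 0.39, but -0.08 in the unsuffixed probe set), TM7SF2 (-2.90, SE 0.32) and the choline transporter family gene SLC44A5 (-2.75, SE 0.46). In BLNK the Kbr cultures read 2.65 ± 0.02 and 2.72 ± 0.08, below the array medians of 2.89 to 2.96, and the controls went from 3.83 ± 1.02 to 7.54 ± 0.52. Its difference therefore reflects the change in controls against background. The Kbr means of EFEMP1 (3.00 ± 0.70), CFB (3.53 ± 0.09) and TM7SF2 (3.90 ± 0.26) at 48 h lay under a log2 value of 4, so background limits the size and the order of these differences. The control means of ZIC2 at both times and of TNFAIP6 at 48 h lay under 4 as well. In TNFAIP6 likewise the controls moved, from 6.06 ± 0.63 to 3.32 ± 0.26, with Kbr cultures at 7.02 ± 0.39 and 6.51 ± 0.58. DDIAS read 6.98 to 7.97 in control arrays at 24 h and 5.26 to 6.58 at 48 h, against 8.68 to 8.81 and 9.14 to 9.26 in Kbr arrays. SLC44A5 read 6.64 to 8.14 and then 8.92 to 9.52 in control arrays, against 5.90 to 6.30 and 4.81 to 5.38 in Kbr arrays. The calls of the 5 positive differences each ended without some single arrays, 10 for SDF2L1, 9 for ZIC2, 8 for DDIAS, 7 for TNFAIP6 and, for CDC6, Kbr 24 h replicate 1 and control 24 h replicate 3; their adjusted p values without those arrays lay between 0.0508 and 0.101. With no expression filter the calls of SDF2L1 (adjusted p = 0.1), TNFAIP6 (0.0806), DDIAS (0.0757) and ZIC2 (0.0941) ended too, and that of TNFAIP6 with an offset of 32 (0.157).

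Among the lists, 12 were called in the difference of effects, 8 upward and 4 downward, and none with an estimated correlation. The unfolded protein response list shifted by a median of 1.03 with 2 of 18 members past the test on their own, SDF2L1 and DNAJB11 (2 adjusted over the list alone; camera adjusted p = 0.000103; adjusted p = 0.485 with an estimated correlation), and the ATF4 list by 0.64 with 0 of 26, also over the list alone (camera adjusted p = 0.0142; adjusted p = 0.657 with an estimated correlation). Both shifts were larger without Kbr 48 h replicate 3 (camera adjusted p = 3.34e-12 and 1.71e-07 at the preset correlation). Without it 13 of 18 and 9 of 26 members passed upward, and the ATF4 median was 1.08. The ATF4 call ended without Kbr 48 h replicate 1 (adjusted p = 0.268) or control 48 h replicate 2 (0.0532) or 3 (0.0783). Immediate early genes shifted by 0.81, 6 of 17 upward and 0 downward (7 and 1 adjusted over the list alone; camera adjusted p = 0.00173; adjusted p = 0.44 with an estimated correlation), with DUSP5 at 1.47. Their medians above the control mean at 48 h were 0.92 and 1.14 in Kbr replicates 1 and 2 and 0.29 in replicate 3. Without that array 7 passed upward and 1 downward, with a median of 1.01 (camera adjusted p = 0.00453). Replication genes, with medians of -0.19 at 24 h and 0.05 at 48 h, shifted by 0.25, 4 of 34 upward and 0 downward (9 and 0 adjusted over the list alone; camera adjusted p = 0.000221; adjusted p = 0.44 with an estimated correlation), with MCM10 at 1.75 besides CDC6, RFC3 and POLA2. Part of this list was lower in control cultures at 48 h than at 24 h, as given below. MCM10 read 8.28 to 8.69 and then 6.54 to 7.69 in control arrays, against 9.36 to 9.47 and 9.68 to 9.86 in Kbr arrays. In CDC6 both moved, controls down and Kbr cultures up. NRF2-type genes shifted by 0.29 with 2 of 25 up, NQO1 and TXN, and 1 down, ABCC3, also over the list alone (camera adjusted p = 0.02; adjusted p = 0.466 with an estimated correlation). That call ended without Kbr 24 h replicate 3 (adjusted p = 0.0745) and with quantile normalization (0.0554). Ribosome biogenesis (0.31, camera adjusted p = 0.0014), proteasome (0.29, 0.0013) and G2 and mitosis genes (0.21, 0.00494) shifted upward as lists with 0 members past the test, also over the list alone. Their adjusted p values with an estimated correlation were 0.44, 0.535 and 0.568. From 24 h to 48 h the mitosis median moved by -0.39 in Kbr and -0.60 in control cultures, so the list fell in both, less in Kbr. The named proteasome genes PSMC1, PSMC4, PSMC6 and PSMD12 had lower control means at 48 h than at 24 h. So did the named ribosome biogenesis genes NOP2, RRP12, RRS1 and WDR43. The mitosis call ended without Kbr 48 h replicate 3 (adjusted p = 0.194) or control 24 h replicate 3 (0.0681), and the proteasome call with probe sets averaged (0.223).

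Of the lists shifting downward, metallothionein genes moved by -1.09 with 5 of 8 members past the test (7 adjusted over the list alone; camera adjusted p = 0.000103; adjusted p = 0.44 with an estimated correlation), MT1M by -1.59 and MT1F by -1.34. Proximal tubule genes moved by -0.80 with 2 of 8 (6 adjusted over the list alone; camera adjusted p = 0.000361; adjusted p = 0.211 with an estimated correlation), AGT by -1.59 and CDH6 by -1.51. This list had a positive median in control cultures from 24 h to 48 h, as given below, which adds to the shift. CDH6 read 12.5 to 13.0 and then 12.3 to 13.0 in control arrays, against 11.3 to 11.9 and 9.74 to 10.3 in Kbr arrays. SLC3A1 read 7.81 to 8.86 and then 9.00 to 9.96 in control arrays, against 6.58 to 6.67 and 6.58 to 7.32 in Kbr arrays. Fatty acid oxidation genes moved by -0.33 with 3 of 17 (6 adjusted over the list alone; camera adjusted p = 0.0013; adjusted p = 0.211 with an estimated correlation), ECI1 by -1.01 and ACADVL by -0.94. Interferon-stimulated genes moved by -0.78 with 1 of 14, also over the list alone (camera adjusted p = 0.00221; adjusted p = 0.44 with an estimated correlation), IFIT3 by -1.06 (named after its value was seen). With the replicate block the fatty acid synthesis and ion transport lists were called too (adjusted p = 0.0483 for each, against 0.0547 and 0.0871 without it). Both calls were lost with the block and an estimated correlation (adjusted p = 0.516 and 0.5).

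The interaction test called 590 genes, 221 with a more positive and 369 with a more negative effect at 48 h; 66 and 210 of these differed at least 2-fold (42 and 135 with an offset of 32). With the replicate number as a block it called 2140 genes. The count depended on single arrays: it was 159, 190 and 236 without Kbr 24 h replicates 1, 2 and 3, 255 and 190 without Kbr 48 h replicates 1 and 2, 342 and 136 without control 24 h replicates 2 and 3, and 217 and 248 without control 48 h replicates 1 and 2. Without Kbr 48 h replicate 3 it was 1507 (818 positive and 689 negative), including all 590.

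Control cultures at 48 h were compared with those at 24 h to show the change with time in culture alone. Part of the mitosis and replication genes were called lower at 48 h. In the G2 and mitosis list 16 of 30 fell and 0 rose (29 and 0 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 2.63e-19; adjusted p = 0.216 with an estimated correlation), and in the replication list 12 of 34 fell and 0 rose (25 and 0 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 2.53e-13; adjusted p = 0.194 with an estimated correlation). CCNB1 read 12.67 ± 0.24 and 11.84 ± 0.24, and in Kbr cultures 13.35 ± 0.03 and 13.02 ± 0.14. Proximal tubule genes had a positive median of 0.59 with 0 of 8 past the test (4 adjusted over the list alone; camera adjusted p = 0.00111; adjusted p = 0.194 with an estimated correlation). These list tests of the control cultures were added after the data were seen. Of the other lists, proteasome (adjusted p = 9.61e-06; 0.494 with an estimated correlation), DNA repair (0.00398; 0.194), ATF4 (0.0174; 0.77), matrix and mesenchymal (0.0174; 0.607), sterol (0.024; 0.426), heat shock (0.0385; 0.617), osmotic stress (0.0395; 0.451), ribosome biogenesis (0.0395; 0.636) and ion transport genes (0.0428; 0.426) passed at the preset correlation only. The heat shock genes BAG3, CHORDC1 and HSPH1, like the proteasome and ribosome biogenesis genes named above, had lower control means at 48 h than at 24 h. The sterol genes INSIG1, LSS, MVK and TM7SF2 had higher ones. The largest rises were in BLNK (3.71, SE 0.41), the antisense gene SSTR5-AS1 (2.33, SE 0.25), the GABA transporter SLC6A13 (2.24, SE 0.39) and the basement membrane collagens COL4A3 (2.15, SE 0.43) and COL4A4 (1.98, SE 0.18). The largest falls were in TXNIP (-3.54, SE 0.59), SLN, a regulator of calcium pumps (-3.04, SE 0.59), the collagenase MMP1 (-3.03, SE 0.50), TNFAIP6 (-2.74, SE 0.35) and TAGLN, an actin-binding protein gene (-2.32, SE 0.56). The means at 24 h of BLNK (3.83), SSTR5-AS1 (2.60), COL4A3 (3.06) and COL4A4 (3.05), and those at 48 h of TNFAIP6 (3.32) and TAGLN (3.24), lay under a log2 value of 4, so background limits the size and the order of these changes.

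This comparison called 426 genes, 183 higher and 243 lower at 48 h, or 2202 with the replicate number as a block; its share of falls was 57.0% as deposited and 49.2% after quantile normalization. With only the 6 control arrays in the limma fit it called 0 genes, although 2140 had an unadjusted p under 0.05, and the count was 198 and 28 without control 24 h replicates 1 and 3, 58, 68 and 655 without control 48 h replicates 1, 2 and 3. Calls for all 10 named genes ended in that fit, and single left-out arrays ended those of SLC6A13, COL4A3, TXNIP, SLN, MMP1 and TAGLN, with adjusted p values between 0.0594 and 0.16.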

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

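Of the tests reported in this part, those of swapped labels, of the position between the times in genes that fell or rose, of the lag of Kbr cultures against simulated groups, of scaling for changes of any size and for mitosis genes, of a slower loss of mitosis transcripts, and of splits with the common effect subtracted were chosen only after the result was seen.

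The effect of Kbr differed between 48 h and 24 h in 590 genes by the interaction test, and the genes below are given because that test passed for them. The 12 lists passed it with camera at the preset correlation only, and 0 did with an estimated correlation (2 at an unadjusted p under 0.05), with or without the replicate block. Limma's fry called 10 lists, 3 upward and 7 downward, which included 6 of the 12. The differences of effects (log2, 48 h minus 24 h) were positive in 14 of the named genes: SDF2L1 3.19, TNFAIP6 2.22, CDC6 2.02, DDIAS 1.98, ZIC2 1.94, MCM10 1.75, ADM 1.65, DUSP5 1.47, GDF15 1.44, DNAJB11 1.33, EXO1 1.22, SLC2A1 0.94, RFC3 0.93 and HSPH1 0.63. They were negative in 27: LSS -0.74, KCNJ15 -0.80, ACSS2 -0.90, DCN -0.91, ACADVL -0.94, ECI1 -1.01, MT1E -1.11, SCNN1A -1.17, LUM -1.22, TP53INP1 -1.23, MT1F -1.34, CDH6 -1.51, SGK1 -1.51, AGT -1.59, MT1M -1.59, ENDOD1 -1.63, COL4A4 -1.98, SLC40A1 -2.02, SLC17A3 -2.05, SSTR5-AS1 -2.20, SCEL -2.28, CYS1 -2.35, SLC44A5 -2.75, TM7SF2 -2.90, CFB -3.01, EFEMP1 -3.26 and BLNK -3.64. In COL4A4, SSTR5-AS1 and BLNK the Kbr means lay near or below the array medians at both times, so their differences reflect the change in controls against background. In TNFAIP6, DDIAS, CDC6, MCM10, EXO1, SLC2A1, RFC3, KCNJ15, ACSS2 and SLC44A5 the control means moved more between the times than the Kbr means. In ENDOD1, SLC40A1, SLC17A3, SCEL, TM7SF2, CFB and EFEMP1 the Kbr means at 48 h, and in ZIC2 and TNFAIP6 control means, lay under a log2 value of 4, which limits the size. List medians differed by 0.29 for NRF2-type, 0.64 for ATF4, 1.03 for unfolded protein response, 0.21 for G2 and mitosis, 0.25 for replication, 0.31 for ribosome biogenesis, 0.29 for proteasome and 0.81 for immediate early genes, and by -1.09 for metallothionein, -0.33 for fatty acid oxidation, -0.78 for interferon-stimulated and -0.80 for proximal tubule genes. The ATF4, mitosis, ribosome biogenesis and proteasome lists had 0 members past the test on their own.

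Splits of the arrays were refitted with limma. At 24 h the real split gave 3429 genes and no other of the 10 splits more than 0 (713 at most at an unadjusted p under 0.05). At 48 h the real split gave 6306 and the highest other 1, and in control cultures 426 and 1. In these comparisons 1 of 10 splits gave as many genes, the real one, and 10 splits are too few for a share under 0.05. The 3 other splits that part all 3 replicate numbers, as the real split does, gave 0 genes in each comparison, and those that part 1 number gave at most 0, 1 and 1. For the difference of effects 7 of 100 splits gave at least 590 genes, the real one included, with 4911 as the highest other, so chance was not excluded; a split with 4911 genes points to a structure of the samples, since splits mixing Kbr with control arrays carry the effect common to both times. With that effect subtracted, 1 of 100 splits gave as many, the real one, and the highest other gave 31. All splits were refitted without the replicate block, and those for the difference were not sorted by the replicate numbers they part.

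Kbr 48 h replicate 3 lay apart from the other Kbr 48 h arrays, with unfolded protein response and ATF4 list medians of 0.10 and -0.49 against at least 1.13 and 0.75 in the others. A swap with a Kbr 24 h array would need a 24 h array nearer to the 48 h arrays, and 0 arrays were. A 24 h culture carrying a 48 h label is argued against by its position on the axis from the Kbr 24 h mean (0) to the other Kbr 48 h arrays (1), which was 0.603 over 1402 genes that fall along it (held-out 24 h arrays 0.01 to 0.16) and 0.251 over 1445 that rise (-0.08 to 0.11), although its mean correlation was 0.986 with the Kbr 24 h arrays (0.992 to 0.993 among themselves) and 0.983 with the other Kbr 48 h arrays. A deviation shared by the cultures numbered 3 accounted for 15.2% of its squared deviation, against 15.4% to 49.1% in the other arrays. A weaker or earlier stress response in that culture, a harvest between the 2 times, a different handling of it and an exchange with a sample outside this set stay open, and no biological explanation was tested.

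Falls outnumbered rises at 24 h, 2114 to 1315. For changes of any size the share of falls depended on array scaling, with 43.8% after quantile normalization and 50.7% with median centring. Both rescalings draw rises and falls towards balance by construction, so these shares cannot tell whether scaling is the cause. For changes of at least 2-fold the share stayed at 63.5% and 76.5% under those scalings and at 80.2% with an offset of 32, which argues against scaling, and against stretched low values, as the whole cause. A loss of transcripts in the treated cells stays open as a hypothesis and was not tested.

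Of 30 mitosis genes 15 were higher and 0 lower in Kbr than in control cultures at 24 h and 24 higher and 1 lower at 48 h, while 16 were lower and 0 higher at 48 h than at 24 h in control cultures. The list calls were lost with an estimated correlation (adjusted p = 0.489, 0.462 and 0.216). Scaling is argued against, since the lowest median of the list under the other scalings was 0.34. A lag of Kbr behind control cultures in the change that time brings cannot be told apart from chance: of the 426 genes changed with time in controls, 71.4% differed in the opposite direction at 24 h, within the 17.8% to 82.2% of 1000 simulated unchanged groups that keep the correlation between genes. The simulated groups did not keep the pairing of arrays by replicate number, so this range does not settle the question. A slower loss of mitosis transcripts cannot be told apart from no difference, since the list moved by -0.39 from 24 h to 48 h in Kbr and -0.60 in control cultures but its test passed only at the preset correlation.

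Probe sets for ribosomal RNA, outside the tested genes, gave a higher signal in Kbr than in control arrays, by 0.49 at 24 h and 0.51 at 48 h for 18S and by 0.38 and 0.46 for 28S. Among 1921 probe sets without a gene symbol, which no comparison used, limma called 284 at 24 h (128 higher and 156 lower) and 774 at 48 h (388 and 386).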

How the results depend on the processing

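Of the alternatives given here, only the estimated correlation with the replicate block, and the list counts without Kbr 48 h replicate 3, were chosen after seeing the data. With an adjusted p under 0.01 the counts were 1830 at 24 h, 32 for the difference of effects, 31 for control cultures and 1750 for genes changed alike at both times, and with a change of at least 2-fold they were 766 at 24 h, 2475 at 48 h, 276 and 98. With no expression filter, where more genes share the correction, the difference gave 386 and control cultures 230. Counting each probe set gave 5227 at 24 h, 10837 at 48 h and 904 for the difference. Counted as genes by their smallest adjusted p, that fit gave 3767, 6968 and 787, so repeated genes account for only part of the rise. Array weights gave 1777 for the difference; the cause was not tested. With only the control arrays in the fit, and so fewer arrays behind the spread, limma called 0 genes between control cultures (2140 at an unadjusted p under 0.05). With the replicate block, which removes the deviation shared by arrays of a number, the difference gave 2140 and control cultures 2202. Among the named genes and lists the block added the calls given beside their values in the report and changed no other call. No list passed with an estimated correlation: the count was 0 at 24 h, 0 at 48 h and 0 for the difference (6, 4 and 2 at an unadjusted p under 0.05), and likewise 0, 0 and 0 with the block added (5, 2 and 2). Limma's fry, which does not compare a list with other genes, called 17 lists at 24 h, 26 at 48 h and 10 for the difference. The p53 list at 48 h had a median of -0.059 and passed downward in fry (adjusted p = 0.00947), opposite to camera's direction. PODXL at 48 h, -0.43 as deposited, was 0.025 after quantile normalization (adjusted p = 0.883); the cause was not tested.

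Leaving out single arrays gave 2255 (without control 24 h replicate 1) to 3231 genes at 24 h, 5599 to 6261 at 48 h, 136 (without control 24 h replicate 3) to 1507 (without Kbr 48 h replicate 3) for the difference, 28 (without control 24 h replicate 3) to 655 (without control 48 h replicate 3) for control cultures and 2148 to 3440 for genes changed alike. List calls then ranged over 9 to 11, 10 to 14 and 11 to 15. Over the named genes 1389 such values kept direction and call, 130 lost the call, 5 gained it and 0 turned; under the other alternatives these were 2752, 76, 36 and 1. For lists they were 676, 18, 26 and 0, and 925, 88, 63 and 1. The number of arrays limits the precision, and signal near background limits the folds of genes at or under a log2 value of 4. In simulated data of 10574 genes with 200 changed, log2 changes of 0.5, 1 and 2 were recovered in 35.8%, 80.6% and 98.5% of cases at 24 h, 20.9%, 76.1% and 97.0% at 48 h, 7.46%, 61.2% and 84.8% for the difference, and 26.9%, 70.1% and 97.0% for control cultures. Far fewer genes changed there than were called at 24 h or 48 h, the noise was independent, and each comparison was drawn once. These rates therefore do not give the power of the real comparisons, nor a difference in power between the times.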

Other observations

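All tests of gene families in this part, and the families themselves, defined by the stem of their symbols (64 with enough tested members), were chosen after the data were seen. Most but not all tested genes of intraflagellar transport, the traffic along cilia, were called lower in Kbr cultures. Of 16 IFT genes 10 fell at 24 h and 0 rose, with a median log2 fold change of -0.50 (camera adjusted p = 0.00751; adjusted p = 0.536 with an estimated correlation). At 48 h 12 fell, with IFT88 at -1.51 (SE 0.17), IFT80 at -1.19 and IFT122 at -1.17, and 1, IFT25 at 0.63, rose, with a median of -0.73 (camera adjusted p = 0.0231; adjusted p = 0.441 with an estimated correlation). Collagen genes fell in 8 of 19 cases at 24 h (median -0.47, camera adjusted p = 0.0265; adjusted p = 0.645 with an estimated correlation) and in 16 of 19 at 48 h (median -1.15, camera adjusted p = 0.00039; adjusted p = 0.441 with an estimated correlation), with 0 rises at either time. Basement membrane members were among them at 48 h, COL4A5 at -2.22, COL4A2 at -1.68 and COL4A1 at -1.13. COL4A3 and COL4A4 were called at 48 h only, with Kbr arrays at 2.57 to 2.59 and 2.92 to 3.01 over both times. Their control arrays read 4.23 to 5.84 and 4.51 to 5.35 at 48 h, so these calls reflect the change in controls against background. Tetraspanin genes fell in 11 of 16 cases at 48 h and rose in 0 (median -0.89, camera adjusted p = 0.0198; adjusted p = 0.467 with an estimated correlation).

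At 48 h the following families had positive medians. Genes with DHX symbols, which are DEAH-box helicases and the antisense gene DHX9-AS1 (0.24, higher), rose in 12 of 16 cases and fell in 0 (median 0.61, camera adjusted p = 0.00689; adjusted p = 0.441 with an estimated correlation), with DHX34 at 1.48 and DHX37 at 1.10. RNA-binding motif genes rose in 17 of 30 cases and fell in 2 (median 0.63, camera adjusted p = 0.0038; adjusted p = 0.441 with an estimated correlation), and genes with POLR symbols, mostly RNA polymerase subunits but also the pseudogene POLR2J4 (-0.45, one of the falls), rose in 17 of 30 and fell in 3 (median 0.39, camera adjusted p = 0.00689; adjusted p = 0.441 with an estimated correlation). Genes with NUP symbols, mostly nucleoporins, rose in 13 of 22 cases and fell in 2 (median 0.45, camera adjusted p = 0.00689; adjusted p = 0.467 with an estimated correlation). Of 331 genes with ZNF symbols, mostly zinc finger genes, 153 rose and 41 fell (median 0.39, camera adjusted p = 3.49e-05; adjusted p = 0.588 with an estimated correlation). Each of these families kept the direction of its median under median centring and quantile normalization.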
